A study of Homo sapiens with 4 samples.

How the data were processed

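Gene expression was measured by droplet-based single-cell RNA sequencing (10x Genomics) in human blood-forming cells kept in culture. Cells of bone marrow and peripheral blood of 1 healthy donor were depleted of mature lineages and cultured for 5 days with stem cell factor (50 ng/mL) and granulocyte colony-stimulating factor (10 ng/mL), per the labels' protocols. Deferasirox (DFX), an oral iron chelator, or its solvent dimethyl sulfoxide (DMSO) was present throughout. The 4 libraries are DMSO 1, DMSO 2, DFX 1.5 µM and DFX 3 µM, so each DFX dose has 1 library. Nothing in the labels says whether the 2 DMSO libraries came from separate cultures. All p-values therefore measure only the spread between these libraries of 1 donor, which may be technical.

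The authors deposited, for each library, a sparse matrix of raw UMI counts per gene and cell barcode, with lists of genes and barcodes. Per the file headers the counts were made with Cell Ranger 7.1.0. The genome build is GRCh38, per the submitters' processing notes, which also name Seurat 3.2.3 with no role. The version of the gene annotation is not given in the sources used here. The matrices hold 36601 features and only barcodes called as cells, the shallowest with 500 UMIs. UMIs are counted molecules, so amplification copies are already collapsed. Reads shared by near-identical genes, such as the HLA class II genes, the alpha defensins and the alpha globins, can be split or lost in such counting, and values of these genes are uncertain in that respect. Gene positions below are those of GENCODE 29 on GRCh38, 1-based.

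The libraries held 4441, 3202, 2613 and 1060 barcodes for DMSO 1, DMSO 2, DFX 1.5 µM and DFX 3 µM, with 21214561, 19070683, 21327843 and 14097864 UMIs. Barcodes with at least 200 genes detected and at most 15% of UMIs from mitochondrially encoded genes were kept. This removed 280, 91, 293 and 131 barcodes for their mitochondrial share. Too few genes were found in 145 barcodes of DFX 1.5 µM and 8 of DFX 3 µM, nearly all of which were also over the mitochondrial limit. Doublets were called with Scrublet in scanpy, per library. It marked 15 of 11316 barcodes, or 0.133%, so it did not work here and doublets remain in the data. After filtering, 4161, 3111, 2305 and 928 cells remained, 10505 in all, with medians of 2294, 3244, 3947 and 9882 UMIs per cell.

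Cells of all libraries were clustered together without batch correction, using scanpy 1.11.5. Counts were scaled to 10000 per cell and log-transformed. The 2000 variable genes, 30 principal components and 15 neighbours fed a Leiden clustering at resolution 1.0. Sex-linked marker genes, 103 in number, were left out of clustering and testing. The 24 clusters were named from marker sets written before the data were examined. A name needed at least 3 markers among the top 50 genes of the cluster, and the 10 leading genes could not hold more markers of another class. A cluster with over 75% of its cells from 1 library stayed unnamed, a limit set after the clusters were seen. Names are written as "-like", and 16 clusters were named. Cells are not replicates, so UMI counts were summed per library over all kept cells and over each class with at least 30 cells in every library, which left 7 classes.

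The summed counts of 2 DFX libraries were compared with those of 2 DMSO libraries by the quasi-likelihood F test of edgeR 4.0.16 (TMM factors, filterByExpr) in R 4.3.3, with 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and all tests are two-sided. With 2 libraries on a side the difference between doses is part of the spread. Fixed gene lists, 35 in number, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 tested members. CPM of genes are UMI counts scaled to the summed library's total over the tested genes, adjusted by its TMM factor. For each dose, the log2 ratio to the mean of both DMSO libraries is given as a value with no test. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. For a count of 0 the limit given is 3 counts of the total, a smaller bound than the upper end of that interval. Shares are given with no test. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, and no model of shares was fitted.

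Named genes were chosen by a rule fixed before the data were examined. In all cells these are up to 12 genes with the highest and 12 with the lowest fold change among genes of at least 20 CPM that passed the test and had both DFX libraries on the same side of both DMSO libraries. In each class the rule takes up to 5 per side with at least 50 CPM. It adds up to 4 members of each list with at least 10 CPM and the largest changes, and 25 genes given in any case. Genes with only a clone name or a LINC number, sex-linked genes and antigen receptor segments were not named, and 1 gene was left out because its presence differs between people. GPX1, a member of the list on peroxide removal, was not analysed here.

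The tests were checked on simulated counts drawn from the real means and library sizes with 200 changed genes. Changed genes had at least 20 CPM, and every gene varied as the trend for its expression. Recovery of lower genes, and calls on genes that vary more than the trend, were therefore not checked. In all cells edgeR recovered 100% of the genes changed 2-fold, with 9 calls among 16720 unchanged genes. It recovered 96% of such genes in the HSPC-like, 97% in the GMP-like, 60% in the myelocyte-like, 22% in the mature neutrophil-like, 73% in the monocyte-like, 62.5% in the macrophage-like and 27.5% in the erythroid-like class. The preset correlation called the 1 shifted list in each of these simulations and 0 of 20 unshifted lists. Genes were drawn independently there, so this cannot show how often the preset makes false calls on lists whose members vary together. With an estimated correlation the shifted list was called in 0 of them, so that setting had little power at this size.

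The alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, dose as a number, counts thinned to the smallest library, each library left out, other filters on cells, and other clusterings. For lists, an estimated correlation and fry were also run. A setting without the clusters dominated by 1 library was added after the data were seen. Before shares were compared across depths, cells were also thinned to 1000 UMIs each, which left out 555, 257, 169 and 66 shallower cells of the 4 libraries in the order above.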

Results

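The series asked how iron chelation by DFX affects myeloid differentiation and the activity of the transcription factor NF-kB in human progenitors driven toward neutrophils. It holds 4 single-cell libraries from cultures of 1 donor: 2 with DMSO, 1 with 1.5 µM DFX and 1 with 3 µM DFX. Kept cells numbered 4161 and 3111 in DMSO 1 and DMSO 2, 2305 at 1.5 µM and 928 at 3 µM, with 20731008, 18861462, 20787536 and 13801663 UMIs in total. Cells were deeper at 3 µM, with a median of 9882 UMIs against 2294 and 3244 in the DMSO libraries. The 2 DMSO libraries differed by more than counting noise (chi-square per degree of freedom 9.36 over 17087 genes), which does not show that they came from separate cultures.

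The composition of the cultures was compared to see which cell types each dose held. Cells resembling hematopoietic stem and progenitor cells (HSPC-like, with SPINK2 among their leading genes) made up 2.72% of cells in DMSO 1 (95% interval 2.24 to 3.26), 2.22% in DMSO 2 (1.73 to 2.80), 5.86% at 1.5 µM (4.93 to 6.89) and 9.59% at 3 µM (7.77 to 11.7). Monocyte-like cells, led by VCAN and FCN1, made up 4.52% and 3.63% in DMSO against 9.33% and 11.9% at 1.5 and 3 µM. Macrophage-like cells, led by CTSB, SPP1 and GPNMB, made up 1.44% and 1.70% against 4.25% and 6.03%. Their ratio of mean DFX to mean DMSO share was smaller, though still above even, with all barcodes and with thinned cells. Mature neutrophil-like cells made up 32.1% (30.7 to 33.6) in DMSO 1, 18.7% (17.4 to 20.1) in DMSO 2, 20.4% (18.8 to 22.1) at 1.5 µM and 9.27% (7.48 to 11.3) at 3 µM. The share at 1.5 µM lay between the DMSO shares. The unnamed cluster 5 takes up 22.0% of DMSO 2. Without it and cluster 23 the DMSO shares were 32.3% and 24.3%, both above the 20.4% at 1.5 µM.

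Among the remaining classes, granulocyte-monocyte progenitor- or promyelocyte-like cells (GMP-like below, with MPO and ELANE) made up 14.9% and 12.2% in DMSO and 17.3% and 13.3% at 1.5 and 3 µM. Their ratio of mean DFX to mean DMSO share, 0.17 on the log2 scale, turned to -0.15 at clustering resolution 1.5 and to -0.17 with called doublets kept. The called doublets were 15 of 11316 barcodes, and the clusters were remade with them. The latter turn therefore came from the remade clusters, not from the added barcodes. Myelocyte- to metamyelocyte-like cells made up 22.2% and 19.0% against 17.3% and 17.0%. Conventional dendritic-like cells made up 0.793% and 0.193% against 1.78% and 3.23%, and erythroid-like cells 1.01% and 2.35% against 2.73% and 4.96%. The unnamed cluster 14 tied between erythroid and promyelocyte markers, with HBB, AHSP, DEFA3 and ELANE among its leading genes, and held 3.75% and 5.01% of the DMSO libraries against 0.217% at 1.5 µM and 0 of 928 cells at 3 µM. Added to the erythroid-like class, it would put DMSO 1 above 1.5 µM and DMSO 2 above both DFX libraries. Cluster 14 had a median of 824 UMIs per barcode, against 3058 over all kept cells, and whether it holds whole cells was not tested. Megakaryocyte- or platelet-like cells numbered 18, 5, 4 and 0, and 0 of 928 cells allows a share of up to 0.323% at 3 µM (3 counts of the total). These shares rest on 1 library per dose and were not tested.

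Unnamed clusters held 19.2%, 39.1%, 19.0% and 21.8% of cells in DMSO 1, DMSO 2, DFX 1.5 µM and DFX 3 µM. Cluster 5, led by ELANE, DEFA4 and CTSG, came almost wholly from DMSO 2, where it held 22.0% of cells against 0.481% in DMSO 1, 0.0434% at 1.5 µM and 0 of 928 cells at 3 µM. Cluster 23, with mast cell genes such as TPSB2 and CPA3, held 1.13% of DMSO 2, 0.0240% of DMSO 1, 0 of 2305 cells at 1.5 µM and 0 of 928 at 3 µM. By 3 counts of the total, a count of 0 allows a share of up to 0.130% and 0.323% in these DFX libraries. Both stayed outside the named classes because 1 library filled them. Most class markers of cluster 5 are those of the GMP-like class, so adding its 22.0% to the 12.2% of that class would put DMSO 2 above both DFX libraries. The named mast- or basophil-like class held 0.625%, 0.707%, 1.91% and 3.02%, so with cluster 23 its share in DMSO 2 comes near that at 1.5 µM. Cluster 9, with LYZ, IRF8 and MKI67 among its leading genes and fewer than 3 markers of any class, held 3.97% and 2.89% of the DMSO libraries and 9.93% and 12.3% at 1.5 and 3 µM.

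**Figure D1:**
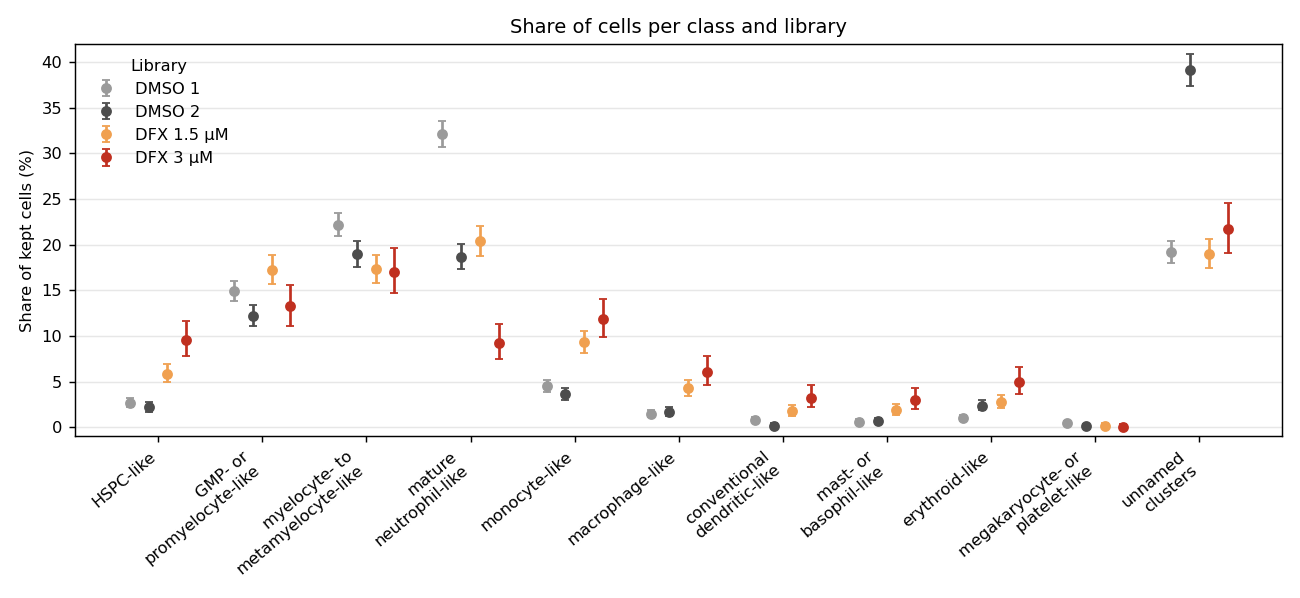
Share of kept cells in percent (vertical axis) per cell class (horizontal axis) in each of the 4 libraries, with points for libraries and bars for exact 95% intervals that cover counting error only. HSPC-like cells stand at 2.72% and 2.22% in the DMSO libraries and at 5.86% and 9.59% at 1.5 and 3 µM, while mature neutrophil-like cells range from 32.1% in DMSO 1 to 9.27% at 3 µM.

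With all cells of a library summed, DFX cultures held less RNA of the neutrophil granule and maturation programs and more RNA of antigen presentation than DMSO cultures. LTF, the lactoferrin of secondary granules, fell with a log2 fold change of -2.22 ± 0.45 (SE, 2 against 2 libraries; edgeR adjusted p = 0.0269), from 215 ± 21.3 CPM in DMSO to 45.8 ± 33.2 in DFX (SD, n = 2 each). CSF3R, the receptor for the growth factor in the medium, fell with -1.33 ± 0.24 (adjusted p = 0.0208). HLA-DRB1, a class II antigen-presenting chain, rose with 1.36 ± 0.12 (adjusted p = 0.00537), from 97.2 ± 14.4 to 250 ± 16.2 CPM. PLIN2, a coat protein of lipid droplets, rose with 1.29 ± 0.13 (adjusted p = 0.00648). LTF lies on chromosome 3 at 46435645 to 46485234, CSF3R on chromosome 1 at 36466043 to 36483278, HLA-DRB1 on chromosome 6 at 32578769 to 32589848 and PLIN2 on chromosome 9 at 19108375 to 19149290.

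Of 17343 genes tested by edgeR in all cells, 645 were higher and 1512 lower with DFX. Among the lists, 12 of 16 tested secondary granule genes fell and 15 fell adjusted over the list alone, with a median log2 change of -1.70. OLFM4 (-1.87 ± 0.38) and TCN1 (-1.87 ± 0.26), which are stored in these granules, fell. LCN2 (-2.01 ± 0.60, adjusted p = 0.0770) did not pass. Of 14 primary granule genes 8 fell and 11 fell adjusted over the list alone, with 1 higher (median -0.70). Of 21 mature neutrophil genes 8 fell and 17 fell adjusted over the list alone (median -1.43), among them MMP25, a leukocyte matrix protease (-1.92 ± 0.32). Of 7 NADPH oxidase genes 4 fell, such as the phagocyte oxidase subunits CYBB (-0.47 ± 0.08) and NCF4 (-0.58 ± 0.07), and 5 fell adjusted over the list alone (median -0.47). Camera called these lists lower (adjusted p = 1.66e-07, 0.000565, 2.77e-06 and 0.0178). Each was lost with an estimated correlation (adjusted p = 0.540, 0.540, 0.589 and 0.540 with an estimated correlation), and that on NADPH oxidase also without DFX 3 µM (adjusted p = 0.0622).

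The other genes with the lowest fold changes were SH3BP5 (-2.53 ± 0.53), the platelet integrin ITGA2B (-2.03 ± 0.43), KREMEN1 (-2.01 ± 0.50), VNN1 (-1.99 ± 0.46), SHOC1 (-1.91 ± 0.17), KCNJ15 (-1.87 ± 0.45), DAPK2 (-1.84 ± 0.22) and PPBP. The platelet chemokine PPBP fell with -4.13 ± 0.95 (adjusted p = 0.0397), from 4428 and 4309 UMIs in the DMSO libraries to 496 at 1.5 µM and 3 at 3 µM. Of 12 megakaryocyte or platelet genes 8 fell and 12 fell adjusted over the list alone. The median was -2.82 and camera gave an adjusted p = 1.99e-05 (adjusted p = 0.540 with an estimated correlation). Megakaryocyte- or platelet-like cells numbered 18 in DMSO 1, 5 in DMSO 2, 4 at 1.5 µM and 0 at 3 µM. These are too few to test within the class, so fewer such cells and a change within them were not told apart.

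Of 12 MHC class II genes 11 rose, and 11 rose adjusted over the list alone, with a median of 1.14 (camera adjusted p = 4.68e-08; adjusted p = 0.540 with an estimated correlation). HLA-DQA1 (1.46 ± 0.20), HLA-DQB1 (1.37 ± 0.14), HLA-DPB1 (1.32 ± 0.15) and HLA-DPA1 (1.20 ± 0.13) were among them. The dendritic-like and monocyte-like classes had larger shares in the same libraries. The other genes with the highest fold changes were ATP10A (1.48 ± 0.18), the mitochondrial carrier SLC25A21 (1.38 ± 0.18), the formyl peptide receptor FPR3 (1.20 ± 0.13), the potassium channel gene KCNQ3 (1.15 ± 0.28) and PRG2, which encodes eosinophil major basic protein (1.13 ± 0.25).

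Lists that mark other cell types were also higher in all cells summed. Of 18 monocyte genes 8 rose, among them CD36 (0.93 ± 0.14), and 2 fell (10 and 2 adjusted over the list alone; median 0.42). Of 17 HSPC genes 6 rose, such as CRHBP (1.11 ± 0.15), and 1 fell (11 and 1 adjusted over the list alone; median 0.47). Of 18 erythroid genes 4 rose (11 adjusted over the list alone; median 0.53). Of 15 macrophage genes 1 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.52), and of 12 mast or basophil genes 1 rose (4 higher and 1 lower adjusted over the list alone; median 0.91). The medians of the macrophage and mast lists between the 2 DMSO libraries, 0.62 and 0.97, were as large, and the macrophage list was not called without DMSO 1 (adjusted p = 0.721) or without DFX 1.5 µM (0.178). Of 83 cytosolic ribosomal protein genes 16 rose (55 adjusted over the list alone; median 0.28), and of 28 interferon response genes 4 rose (9 higher and 1 lower adjusted over the list alone; median 0.28). Camera gave adjusted p = 0.00538, 0.000565, 0.000779, 0.0450, 0.00817, 1.92e-12 and 0.00538 for these lists in turn. None was called there with an estimated correlation (adjusted p = 0.540, 0.540, 0.540, 0.719, 0.691, 0.540 and 0.540 with an estimated correlation), while the rotation test fry gave 0.00734 for the monocyte and for the HSPC list. The transcription factor gene IRF8, active in monocyte and dendritic lineages, rose with 0.57 ± 0.13 (adjusted p = 0.0397). SPI1, which encodes PU.1, fell with -0.32 ± 0.07 (adjusted p = 0.0341).

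The count of genes depended on the DMSO libraries. Without DMSO 1, 58 genes were higher and 345 lower, and without DMSO 2, 261 and 918; of the 28 named genes that passed, 14 and 23 still passed. LTF, CSF3R, PPBP, OLFM4, MMP25, SOD2, FTH1 and SPI1 were among those that did not pass without DMSO 1, and FTH1, SPI1 and IRF8 among those that did not without DMSO 2. DESeq2 kept 21 and lost KCNQ3, PRG2, PPBP, ITGA2B, KREMEN1, VNN1 and KCNJ15. Without DFX 3 µM KCNQ3, SPI1 and IRF8 did not pass, without the clusters dominated by 1 library KCNQ3, FTH1 and SPI1 did not, and with dose as a number FTH1 and SPI1 did not.

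The study's question on NF-kB was addressed with a list of 32 tested NF-kB target genes. In all cells summed 11 fell and 1 rose (13 lower and 4 higher adjusted over the list alone), with a median of -0.38 and a camera adjusted p = 0.00776 (adjusted p = 0.540 with an estimated correlation). SOD2, the mitochondrial superoxide dismutase, fell with -1.13 ± 0.24 (edgeR adjusted p = 0.0326), from 256 ± 75.5 to 117 ± 32.3 CPM. BCL2A1, an anti-apoptotic family member (-1.22 ± 0.28), IRAK2, a kinase of interleukin 1 signalling (-1.15 ± 0.10), and IL1RN, the interleukin 1 receptor antagonist (-1.15 ± 0.23), also fell. The chemokine gene CCL2, named after its value was seen, was the member that rose. The feedback inhibitors NFKBIA (-0.23 ± 0.11, adjusted p = 0.218) and TNFAIP3 (-0.11 ± 0.19, 0.743) did not pass, nor did CXCL8 (1.03 ± 0.30, 0.0753) and IL1B (0.52 ± 0.14, 0.0548). The median was -0.45 at 1.5 µM and -0.29 at 3 µM, against -0.14 between the DMSO libraries. Against DMSO 1 alone the value at 3 µM was -0.50. Without DFX 1.5 µM the list's adjusted p was 0.108.

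Within classes the NF-kB list was not called lower in any of the 7. Its medians were -0.06 in HSPC-like (adjusted p = 0.178), -0.08 in GMP-like (0.301), -0.11 in myelocyte-like (0.269), -0.07 in mature neutrophil-like (0.862), 0.04 in monocyte-like (0.621) and -0.04 in erythroid-like cells (0.754). Without DFX 1.5 µM the list was called lower in myelocyte-like cells (adjusted p = 0.0471). In macrophage-like cells it was higher, with a median of 0.33 over 23 genes, of which 1 rose and 3 rose adjusted over the list alone (camera adjusted p = 0.000224; adjusted p = 0.861 with an estimated correlation). CXCL8, a neutrophil chemoattractant, was the member that rose there (1.25 ± 0.25, edgeR adjusted p = 0.00941), with 199 ± 110 CPM in DMSO and 468 ± 211 in DFX. The call on the list was lost without DMSO 2 (adjusted p = 0.202) and without DFX 3 µM (0.495). Its median was 0.07 at 1.5 µM and 0.59 at 3 µM.

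Iron and redox genes were examined because the compound binds iron. Of 20 tested iron handling genes 2 rose and 1 fell (2 and 2 adjusted over the list alone; median 0.03), and camera did not call the list (adjusted p = 0.436). FTH1, the ferritin heavy chain, rose with 0.43 ± 0.09 (edgeR adjusted p = 0.0291), and TFR2, named after its value was seen, was the other that rose. FTH1 is among the leading genes of the macrophage-like cluster 15 and of the unnamed cluster 16, which held 1.59% and 2.25% of the DMSO libraries and 2.73% and 3.88% at 1.5 and 3 µM. Cluster 16 was shallow, with a median of 1131 UMIs per barcode. The macrophage-like share was larger with DFX as well. FBXL5, the iron-sensing subunit of a ubiquitin ligase, fell with -0.79 ± 0.09 (adjusted p = 0.00735). In DMSO it stood at 1347 ± 38.8 CPM in myelocyte-like cells and at 140 ± 5.73 in erythroid-like cells. Its changes within these classes were -0.28 ± 0.11 and -0.61 ± 0.25 (edgeR adjusted p = 0.359 and 0.544). How much of its fall in the sum follows the mix of classes was not tested. The transferrin receptor gene TFRC stood at 253 ± 0.686 CPM in DMSO and 265 ± 8.22 in DFX (0.07 ± 0.07, adjusted p = 0.582), and FTL at 0.25 ± 0.09 (0.130). HMOX1, encoding heme oxygenase (0.37 ± 0.12, 0.0900), and NQO1 (-0.04 ± 0.15, 0.882), both targets of NRF2, did not pass. Of 30 targets of the hypoxia-inducible factor 9 fell, such as the glucose transporter gene SLC2A3 (-1.39 ± 0.22) and the glycolytic regulator PFKFB3 (-0.95 ± 0.08), and 11 fell adjusted over the list alone (median -0.25; camera adjusted p = 0.00121; adjusted p = 0.540 with an estimated correlation). SLC2A3 is among the leading genes of the mature neutrophil-like clusters 1 and 8, and that class had its smallest share at 3 µM. Of 13 mitochondrially encoded genes 1 fell (3 adjusted over the list alone; median -0.20; adjusted p = 0.0450; 0.540 with an estimated correlation), a call lost without DMSO 1, DMSO 2, DFX 1.5 µM or DFX 3 µM (adjusted p = 0.0932, 0.108, 0.0825 and 0.109). Of 76 nuclear-encoded respiratory chain genes 2 rose (1 adjusted over the list alone; median 0.10; adjusted p = 0.00273; adjusted p = 0.691 with an estimated correlation; 0.347 without DFX 1.5 µM).

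The lists of heme synthesis (median 0.14, adjusted p = 0.167), iron-sulfur cluster assembly (0.14, 0.118), glycolysis (-0.02, 0.147), NRF2 targets (0.01, 0.642), superoxide and peroxide removal (0.05, 0.579), the ATF4 stress response (-0.01, 0.769), eosinophils (0.96, 0.0551), B or plasma cells (-0.11, 0.852), plasmacytoid dendritic cells (0.14, 0.859), immediate early and heat shock genes (-0.31, 0.227), apoptosis (-0.01, 0.796) and myeloid regulators (-0.06, 0.640) were not called by camera in all cells. For the ATF4, peroxide removal, B or plasma cell and plasmacytoid dendritic lists the median and the mean differed in sign. S phase genes (41 tested, median 0.09, adjusted p = 0.0183) and G2 and M phase genes (52 tested, median -0.13, adjusted p = 0.0183) were called with small medians, 0 members passed in either by edgeR, over all genes or adjusted over the list alone, and both had adjusted p = 0.691 with an estimated correlation. The S phase call was lost without DMSO 1 or DFX 1.5 µM (adjusted p = 0.471 and 0.229), and the G2 and M phase call without DMSO 1, DMSO 2 or DFX 3 µM (0.0645, 0.0765 and 0.540). The list of T or NK cells had too few detected members to test.

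**Figure D2:**
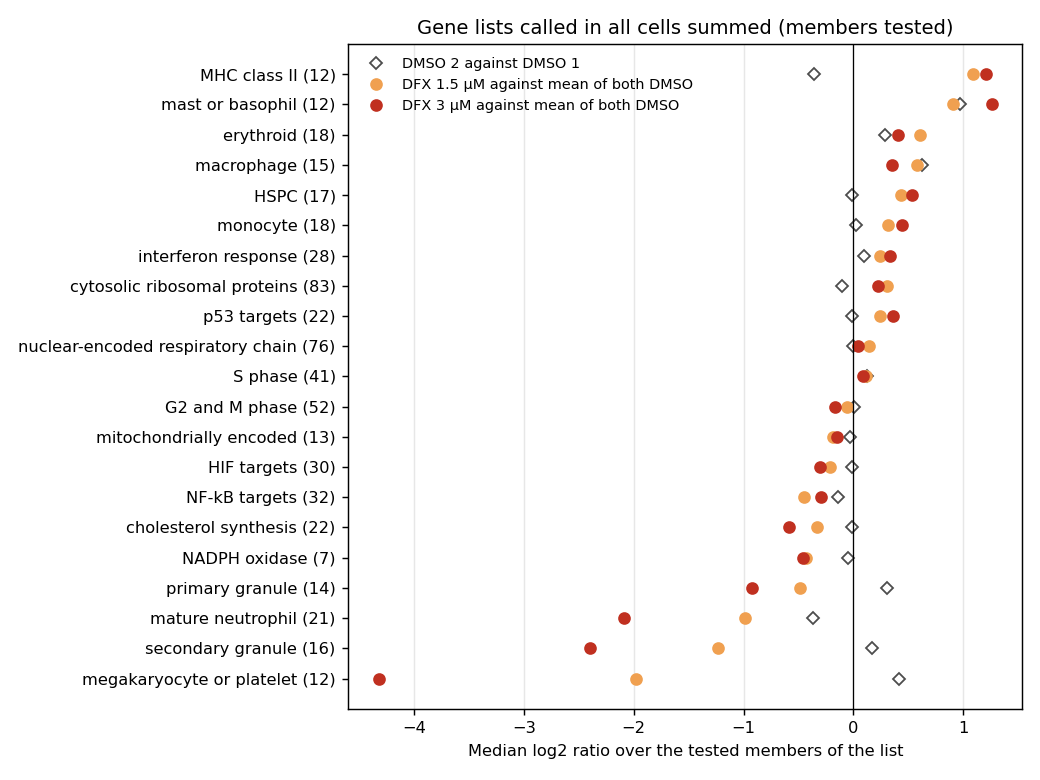
Median log2 ratio over the tested members (horizontal axis) of each gene list called by camera in all cells summed (vertical axis, members tested in brackets), for DFX 1.5 µM and DFX 3 µM against the mean of both DMSO libraries and, as open diamonds, for DMSO 2 against DMSO 1. The secondary granule list lies at -1.23 and -2.40 for the 2 doses and MHC class II at 1.09 and 1.21, while the platelet list at 3 µM rests on genes with few UMIs.

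Changes within a class were examined to separate them from changes in the mix of classes. In GMP-like cells, 9 of 22 targets of the tumour suppressor p53 were higher and 6 of 22 genes of cholesterol synthesis lower with DFX. Camera called both lists, and both calls were lost with an estimated correlation (adjusted p = 0.551 for each with an estimated correlation). The class leaves out the unnamed cluster 5, with 683 cells of DMSO 2 against 381 in the class. How these results change with that cluster was not tested. Against DMSO 1 alone, with 20 cells of cluster 5, the p53 medians at 1.5 and 3 µM were 0.44 and 0.84. The cholesterol synthesis medians were -0.30 and -0.67. CDKN1A, the cell cycle inhibitor p21, rose from 8.85 ± 0.781 to 45.3 ± 18.9 CPM (log2 fold change 2.29 ± 0.23, edgeR adjusted p = 6.18e-06). MDM2, the ubiquitin ligase that limits p53, rose from 159 ± 0.714 to 423 ± 179 CPM (1.41 ± 0.18, adjusted p = 9.21e-05). HMGCS1, an early enzyme of cholesterol synthesis, fell from 85.7 ± 8.99 to 38.2 ± 7.69 CPM (-1.14 ± 0.14, adjusted p = 6.83e-05). CDKN1A lies on chromosome 6 at 36676460 to 36687339, MDM2 on chromosome 12 at 68808176 to 68850686 and HMGCS1 on chromosome 5 at 43289395 to 43313512.

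Of 22 p53 targets in GMP-like cells 9 rose and 17 rose adjusted over the list alone, with a median of 0.55 (camera adjusted p = 5.42e-14; adjusted p = 0.551 with an estimated correlation). FDXR, a mitochondrial electron carrier for iron-sulfur cluster and steroid synthesis (1.10 ± 0.16), PHLDA3 (1.39 ± 0.25) and ZMAT3 (1.02 ± 0.16) were among them. The list's median was 0.45 at 1.5 µM and 0.80 at 3 µM against -0.02 between the DMSO libraries. Of 22 cholesterol synthesis genes 6 fell and 15 fell adjusted over the list alone, with a median of -0.40 (camera adjusted p = 4.34e-11; adjusted p = 0.551 with an estimated correlation), among them INSIG1, a sterol-sensing regulator (-1.05 ± 0.14), LSS (-0.96 ± 0.17) and MVD (-0.83 ± 0.17). This median was -0.25 at 1.5 µM and -0.64 at 3 µM against -0.13 between the DMSO libraries. The fatty acid desaturase FADS2 (-1.18 ± 0.15) and CD24 (-1.18 ± 0.18) also fell, and CYTL1 (1.21 ± 0.16), HIP1 (1.18 ± 0.20) and TAFA2 (1.06 ± 0.14) rose. Granulocyte genes were lower in this class as well: S100A8 (-1.74 ± 0.13), S100A9 (-1.70 ± 0.13) and DEFA3 (-1.40 ± 0.24) fell, as did 11 of 13 secondary granule genes, and 13 adjusted over the list alone (median -2.12; camera adjusted p = 3.39e-15; adjusted p = 0.551 with an estimated correlation). Cluster 10, with DEFA4, CEACAM6 and CD24 among its leading genes, held 232 of 622 and 174 of 381 cells of the class in DMSO. With DFX it held 97 of 398 at 1.5 µM and 31 of 123 at 3 µM. Whether the lower granulocyte genes and CD24 follow this mix of clusters, or free RNA, was not tested in this class.

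Both lists were also called in all cells summed. Of 22 p53 targets 7 rose and 1 fell there (12 and 2 adjusted over the list alone; median 0.27; camera adjusted p = 0.00582), and of 22 cholesterol synthesis genes 11 fell (17 adjusted over the list alone; median -0.45; 1.31e-06). Both had adjusted p = 0.540 with an estimated correlation.

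In all, edgeR called 70 genes higher and 144 lower of 12447 in GMP-like cells. DESeq2 called 27 and 48, and MDM2, HIP1, DEFA3 and CD24 did not pass there. Cluster 3, led by MPO, held most of this class with DFX (12.1% of all cells at 1.5 µM and 9.48% at 3 µM, against 4.21% and 3.34% for cluster 10), while clusters 3 and 10 held 8.22% and 5.58% of DMSO 1 and 5.11% and 5.59% of DMSO 2. Cluster 18, with 48, 48, 22 and 4 cells, is also in this class, with CTSG among its leading genes but also immunoglobulin genes, which are in none of the marker sets.

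**Figure D3:**
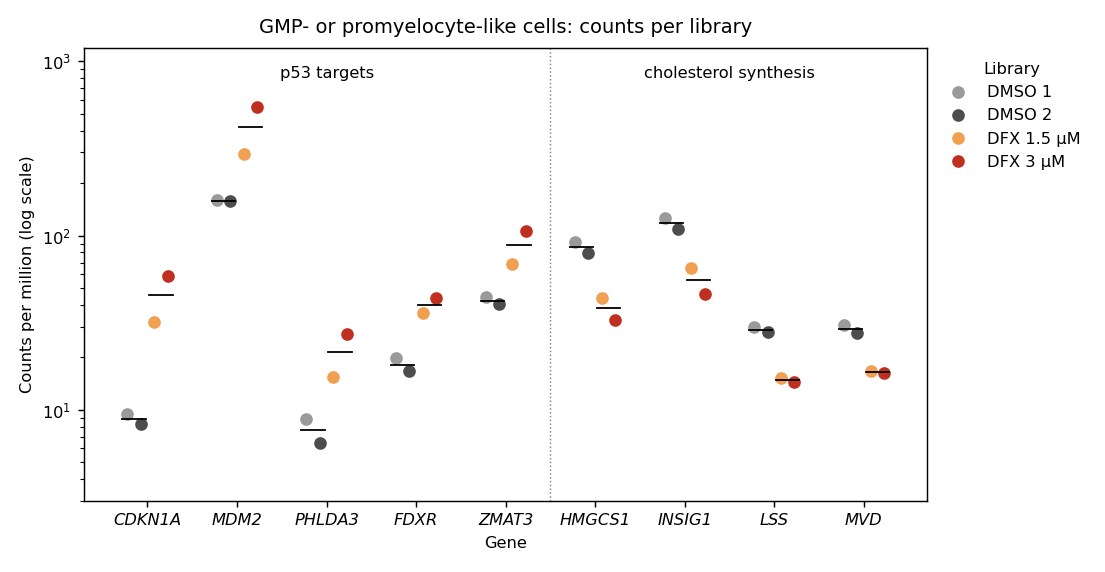
CPM on a log axis (vertical) of 5 p53 targets and 4 cholesterol synthesis genes (horizontal) in GMP-like cells, with a point for each library and black lines for the means of the 2 DMSO and the 2 DFX libraries. MDM2 stands at 159 and 158 in the DMSO libraries, 296 at 1.5 µM and 549 at 3 µM, and HMGCS1 is below both DMSO libraries at both doses.

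In HSPC-like cells 9 of 52 genes of the G2 and M phases of cell division were lower with DFX (adjusted p = 0.50 for the list with an estimated correlation). TOP2A, the mitotic topoisomerase and a member of the list, fell from 220 ± 46.8 to 104 ± 25.1 CPM (-1.10 ± 0.18, edgeR adjusted p = 0.00491). CCNB1, the mitotic cyclin B1, which is not on the list, fell from 76.9 ± 2.31 to 31.2 ± 2.50 CPM (-1.29 ± 0.16, edgeR adjusted p = 0.000307). Of 52 G2 and M phase genes 9 fell and 38 fell adjusted over the list alone (median -0.55; camera adjusted p = 9.57e-28; adjusted p = 0.50 with an estimated correlation). Of 21 p53 targets 1 rose, the DNA damage sensor DDB2 (0.74 ± 0.16), and 7 rose adjusted over the list alone (median 0.51, with 0.33 at 1.5 µM and 0.67 at 3 µM; camera adjusted p = 1.06e-09; adjusted p = 0.637 with an estimated correlation). MAGI2 (0.86 ± 0.18) and CYTOR (0.76 ± 0.16) rose, and the kinetochore motor gene CENPE (-1.13 ± 0.19), S100A9 (-1.98 ± 0.26) and S100A8 (-1.97 ± 0.34) fell. Of 12244 genes tested 10 were higher and 42 lower. DESeq2 called 1 and 15, and without DFX 1.5 µM edgeR called 107. Of the 8 named genes 3 passed without DMSO 1, CCNB1, CENPE and S100A9, and 4 without DMSO 2, CCNB1, TOP2A, S100A8 and S100A9. CENPE and TOP2A did not pass without DFX 1.5 µM, nor MAGI2, CYTOR and DDB2 without DFX 3 µM. MAGI2, CYTOR, DDB2, S100A8 and S100A9 did not pass with DESeq2, and CYTOR, DDB2, CENPE and TOP2A did not with dose as a number. The class could not be named at clustering resolution 0.6, without cell cycle genes or with DMSO clusters. The G2 and M phase result was therefore not checked on clusters made without those genes.

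In myelocyte- to metamyelocyte-like cells edgeR called 0 of 9441 genes, with 1124 at an unadjusted p under 0.05, and DESeq2 called 4. With dose as a number edgeR called 123. SLC7A11, the cystine transporter, stood at 2.04 ± 0.47 (edgeR adjusted p = 0.274), PSAT1 at 1.09 ± 0.27 and MTHFD2 at 0.95 ± 0.19, enzymes of serine and folate metabolism. The ATF4 stress list to which they belong was called higher, with 4 of 13 members higher adjusted over the list alone and 0 over all genes (median 0.90; camera adjusted p = 7.19e-07; adjusted p = 0.694 with an estimated correlation). The p53 list was also called higher (17 tested, 4 higher adjusted over the list alone, 0 over all genes; median 0.23; adjusted p = 0.0198; adjusted p = 0.813 with an estimated correlation). That call was lost without DMSO 1, DFX 1.5 µM or DFX 3 µM (adjusted p = 0.131, 0.289 and 0.0526). Cholesterol synthesis genes were called lower (19 tested, 7 lower adjusted over the list alone, 0 over all genes; median -0.39; adjusted p = 7.88e-05; adjusted p = 0.813 with an estimated correlation). At 3 µM clusters 2 and 12 held this class (10.1% and 6.25% of all cells) and cluster 11, led by LTF, 0.647% against 6.30% in DMSO 1.

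In mature neutrophil-like cells edgeR called 0 of 7901 genes, with 247 at an unadjusted p under 0.05, and DESeq2 called 0. Cluster 1 held most of the class at 3 µM (7.97% of 9.27%), while clusters 1, 4 and 8 shared it in DMSO 1 (12%, 11.6% and 8.48%). The G2 and M phase list was called lower (26 tested, 0 over all genes and 0 adjusted over the list alone; median -1.13, and -0.41 between the DMSO libraries; camera adjusted p = 4.33e-08; adjusted p = 0.975 with an estimated correlation). Members such as CENPE and TOP2A had few UMIs at 3 µM. Without DMSO 2 edgeR called 3 genes, without DFX 1.5 µM 513 and without DFX 3 µM 30. Only 86 cells of this class were kept at 3 µM, and 2-fold changes were recovered there in 22% of simulated cases, so most changes of that size were not detectable at this depth.

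In monocyte-like cells DEFA3, ABCA13 and OLFM4, granulocyte genes, fell (-2.38 ± 0.23, -2.51 ± 0.26 and -3.27 ± 0.37) and were the only 3 of 9664 genes called by edgeR; DESeq2 called 6. Without DMSO 1, DMSO 2 or DFX 1.5 µM edgeR called 41, 33 and 54. The G2 and M phase list was called lower (27 tested, 0 over all genes and 9 adjusted over the list alone; median -0.51; camera adjusted p = 1.46e-11; adjusted p = 0.587 with an estimated correlation), but not with clusters made from the DMSO cells alone (0.917). The monocyte MHC class II list was lower (11 tested, 0 passed; median -0.23; camera adjusted p = 0.00861; adjusted p = 0.587 with an estimated correlation), but higher, with an adjusted p = 5.32e-08, when clusters were made from the DMSO cells alone. It was not called without DMSO 1, DFX 1.5 µM or DFX 3 µM (adjusted p = 0.439, 0.123 and 0.0535). In macrophage-like cells PLIN2 (1.39 ± 0.20), CD52 (1.82 ± 0.27), the potassium channel gene KCNQ3 (1.74 ± 0.30) and PDK4, a brake on pyruvate oxidation (1.56 ± 0.30), rose, and DEFA3 (-2.14 ± 0.23), ABCA13 (-1.86 ± 0.29), DEFA4 (-1.79 ± 0.28), SELENOP (-1.13 ± 0.25) and FAR2 (-1.06 ± 0.24) fell, among 11 higher and 15 lower of 8407. HBB, the red cell globin, had 8 and 10 UMIs there in DMSO, 19 at 1.5 µM and 481 at 3 µM, so its rise (4.24 ± 0.70) came from 1 library and was lost without it. DESeq2 called 3 and 1 in this class, and without DMSO 1 or DFX 1.5 µM edgeR called 69 and 75. SELENOP and FAR2 did not pass without DMSO 2 or without DFX 3 µM, PDK4 did not without DFX 3 µM, and FAR2 did not without DFX 1.5 µM. Of the 10 named genes CD52, PLIN2 and DEFA3 passed with DESeq2. HBB, PDK4, SELENOP and FAR2 did not pass at clustering resolution 0.6.

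In erythroid-like cells S100A8 (-5.53 ± 0.87), S100A9 (-5.05 ± 0.81), CTSG (-4.76 ± 0.78), RETN (-4.72 ± 0.62) and ELANE (-4.22 ± 0.78) fell, and CCDC26, a long non-coding RNA, rose (1.40 ± 0.27). Of 11 primary granule genes 9 fell and 10 fell adjusted over the list alone (median -3.53, and 2.32 between the DMSO libraries; camera adjusted p = 7.61e-13; adjusted p = 0.665 with an estimated correlation). Of 5 mature neutrophil genes 4 fell, and 4 fell and 1 rose adjusted over the list alone (median -3.95; 0.000315; adjusted p = 0.665 with an estimated correlation). S100A8 had 121 UMIs in this class in DMSO 1, 2429 in DMSO 2, 60 at 1.5 µM and 27 at 3 µM. Of 6226 genes 2 were higher and 52 lower by edgeR, and 1 and 28 by DESeq2. With counts thinned to the smallest library edgeR called 0, and with each library left out (DMSO 1, DMSO 2, DFX 1.5 µM, DFX 3 µM) 257, 83, 94 and 101. S100A8, S100A9, CTSG and ELANE did not pass with DESeq2, and CCDC26 did not without DFX 1.5 µM or with dose as a number.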

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

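Of the tests in this part, the choice of class pairs and lists for the differences between classes, the count of classes with higher NF-kB targets and the comparison of p53 targets with monocyte-like and erythroid-like cells were chosen only after the results were seen.

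Differences between classes in the DFX effect were tested with camera on the differences themselves, in 20 tests over 4 pairs of classes. Of these, 9 passed and 0 passed with an estimated correlation, where the lowest adjusted p was 0.310. The p53 effect was larger in GMP-like than in monocyte-like cells by a median log2 difference of 0.69 (19 of 19 genes; adjusted p = 3.57e-12). It was larger in HSPC-like than in monocyte-like cells by 0.62 (18 of 18 genes; 4.63e-09) and in GMP-like than in myelocyte-like cells by 0.29 (15 of 17 genes; 0.000551). Cholesterol synthesis genes differed by -0.35 between GMP-like and monocyte-like cells (6.68e-06). G2 and M phase genes differed by 0.48 for that pair, their medians being lower in monocyte-like cells (4.63e-09). Mature neutrophil genes differed by -0.79 between GMP-like and monocyte-like cells (2.43e-08), by -1.71 between HSPC-like and monocyte-like cells (5.95e-06) and by -0.96 between GMP-like and myelocyte-like cells (5.95e-06). The value for HSPC-like cells rests on 7 genes of a list that holds S100A8 and S100A9. In DMSO 1 these had 21.2 UMIs per HSPC-like cell and 193 per monocyte-like cell. Whether less free granulocyte RNA with DFX underlies these differences was not tested. NF-kB targets differed by 0.26 between macrophage-like and monocyte-like cells (14 of 21 genes; 0.0457).

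Barcodes over the mitochondrial limit, which the comparisons leave out, made up 11.2% (exact 95% interval 10.0 to 12.5) of DFX 1.5 µM and 12.4% (10.4 to 14.5) of DFX 3 µM, against 6.30% (5.61 to 7.06) and 2.84% (2.29 to 3.48) of DMSO 1 and DMSO 2. Their median mitochondrial share was 79.8% and 34.9% in the DFX libraries against 22.9% and 23.8%.

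A set of 15 genes, of which 8 are in a granule or neutrophil list (S100A8, S100A9, DEFA3 and OLFM4 among them), was called lower in at least 2 of the HSPC-like, monocyte-like, macrophage-like and erythroid-like classes. A few doublets or wrongly clustered cells are argued against as the whole cause: without the 10% of cells with the highest share of these UMIs the median log2 ratio was -1.32, against -1.67 with them. Free RNA from neutrophil-lineage cells stays open. It would add like counts to every class. The largest ratio of these UMIs per cell between HSPC-like, macrophage-like and erythroid-like cells had a median of 3.98 over the libraries. It ranged from 2.18 in DMSO 2 to 13.5 at 3 µM. Monocyte-like cells were left out of this ratio. They held 209, 199, 225 and 241 such UMIs per cell in DMSO 1, DMSO 2, DFX 1.5 µM and DFX 3 µM. Of these, 193, 177, 212 and 225 were of S100A8 or S100A9. Macrophage-like cells hold S100A8 and S100A9 UMIs of their own. In the same order they held 49.4, 76.7, 48.1 and 95.6 pattern UMIs per cell, with 38.55, 59.2, 40.7 and 87.0 of these genes. HSPC-like cells held 39.1, 35.1, 16.7 and 14, with 21.2, 11.8, 6.09 and 3.16. Erythroid-like cells held 17.8, 73.1, 9.27 and 7.07, with 5.29, 54.0, 1.89 and 1. The ratio was not computed without these genes and cannot decide as it stands. A change in the cells themselves stays open too.

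NF-kB targets had a median of -0.38 in all cells summed. Lower expression within every class stays open: 2 of the 7 tested classes, monocyte-like and macrophage-like, had a median above 0, but the former was 0.04 and the call in the latter was lost without DMSO 2 or DFX 3 µM (adjusted p = 0.202 and 0.495). With each cluster's profile held at its pooled DMSO counts and only the cluster shares changed, the predicted median was -0.26, on log2 CPM without TMM factors. A candidate explanation for much of the lower sum is therefore fewer UMIs from clusters rich in these genes. Clusters are defined by expression, and the list member SOD2 is among the leading genes of the mature neutrophil-like clusters 4 and 8. The prediction therefore cannot separate a change in cell types from lower expression within a cell type. Whether the shift between clusters is a response to DFX or spread between libraries stays open with 1 library per dose.

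The p53 targets had a median of 0.55 in GMP-like cells. A change in the mix of clusters within the class is argued against, since with cells pooled within a library the median log2 ratio was 0.48 in cluster 3 and 0.50 in cluster 10, with 22 of 22 genes above 0 in each, and 14 of 22 in the small cluster 18. Cells of extreme depth are argued against as the source. The median was 0.40 among cells with 4933.75 to 17554.5 UMIs and 0.40 by the same measure over the whole class. Depth was not matched between libraries within that range, which held 39 of 123 cells at 3 µM, so an effect of depth inside it stays open. Free RNA shared by all droplets is argued against, since the higher of the medians in monocyte-like and erythroid-like cells was -0.067. A hypothesis is that DFX may raise p53 activity in these progenitors, found and tested on the same libraries of 1 donor, and a difference between the cultures other than DFX was not tested.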

How the results depend on the processing

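The setting without clusters dominated by 1 library was chosen after seeing the data. No paired analysis was possible because the labels pair no DMSO library with a DFX library. With a library left out, the lone library of its group is assumed to vary like the other group. Except where stated, the cause of a difference was not tested.

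Counts of genes for all cells summed, 645 higher and 1512 lower, stayed within 1.5 times under RLE, DESeq2, dose as a number, thinning and the filters on cells. With no filter on low counts they were 1326 and 2395. With a library left out they ranged from 58 to 940 higher and from 345 to 1867 lower, lowest without DMSO 1. With no filter edgeR called 142 genes in HSPC-like (main value 52), 354 in GMP-like (214), 21 in mature neutrophil-like (0), 93 in monocyte-like (3), 67 in macrophage-like (26) and 223 in erythroid-like cells (54). DESeq2 called 16, 75, 6, 4 and 29 in the HSPC-like, GMP-like, monocyte-like, macrophage-like and erythroid-like class, and 4 in the myelocyte-like class (0). Dose as a number gave 123 in myelocyte-like, 35 in monocyte-like and 73 in macrophage-like cells. Thinning to the smallest library gave 12 in monocyte-like, 13 in macrophage-like and 0 in erythroid-like cells by edgeR (main value 54, with 491 at an unadjusted p under 0.05, and 29 by DESeq2 without thinning), with fewer UMIs by construction. Keeping the called doublets, 15 of 11316 barcodes, and remaking the clusters gave 1 in monocyte-like and 14 in macrophage-like cells. Resolution 0.6 gave 7 in macrophage-like cells, and clusters from DMSO cells alone gave 7 in monocyte-like and 94 in erythroid-like cells. With each library left out the counts ranged from 42 to 107 in HSPC-like, 0 to 513 in mature neutrophil-like, 3 to 54 in monocyte-like, 23 to 75 in macrophage-like and 83 to 257 in erythroid-like cells; they were highest without DFX 1.5 µM, except in erythroid-like cells, where they were highest without DMSO 1.

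With an estimated correlation camera called 0 lists in all cells (21 with the preset) and 0 in each of the 7 classes (9, 12, 9, 4, 9, 6 and 5), and fry called 2 in all cells. The simulated shifted list was missed too, so this setting had little power. Simulated genes were independent, so the preset calls were not checked for lists whose members vary together. For NF-kB targets in all cells the adjusted p was 0.540 with an estimated correlation and 0.143 with fry, and with a library left out it ranged from 0.00268 to 0.108. With a library left out the lists called ranged from 5 to 17 in myelocyte-like, 4 to 8 in mature neutrophil-like and 6 to 10 in erythroid-like cells, and clusters from DMSO cells gave 8 in erythroid-like cells. The mitochondrially encoded list turned upward with all barcodes (adjusted p = 0.476), which adds barcodes rich in these genes. In monocyte-like cells S phase (0.000335), MHC class II (5.32e-08) and HSPC genes (0.738) turned with clusters from DMSO cells. With a library left out, adjusted p ranged from 1.68e-12 to 0.966 for respiratory chain and from 5.30e-17 to 0.966 for ribosomal protein genes there, both turning without DMSO 2. It ranged from 1.18e-10 to 0.131 for ribosomal protein genes in myelocyte-like cells, turning without DFX 3 µM.

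The log2 ratio of GMP-like shares, 0.17, became -0.15 at resolution 1.5, -0.17 with doublets kept and clusters remade, and -0.020 without clusters dominated by 1 library. That of myelocyte-like shares, -0.26, became -0.037 with all barcodes, -0.41 with thinned cells and -0.45 without such clusters. That of macrophage-like shares, 1.71, became 1.06 with all barcodes and 1.24 with thinned cells. The other shares moved by less than the spread between pairs of libraries. Some alternatives gave no value because no cluster could be named: HSPC-like at resolution 0.6, without cell cycle genes and with DMSO clusters; macrophage-like at resolution 1.5 and with DMSO clusters; dendritic-like at resolution 0.6, with DMSO clusters and thinned; mast-like with DMSO clusters and thinned.

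At 3 µM the NF-kB median in all cells, -0.29, was -0.50 against DMSO 1 alone. In HSPC-like cells the G2 and M phase medians, -0.60 and -0.49 at 1.5 and 3 µM, were -0.44 and -0.31 against DMSO 2 alone. The p53 median in GMP-like cells at 3 µM, 0.80, was 0.84 against DMSO 1 and 0.76 against DMSO 2 alone. Over named genes and alternatives, 894 values kept their side of the threshold, 102 no longer passed, 36 passed newly and 3 moved. Thinning to the smallest library ended the calls of 1 named gene in HSPC-like, 2 in macrophage-like and 6 in erythroid-like cells. With called doublets kept and clusters remade, 1 named gene no longer passed in each of the HSPC-like, GMP-like, monocyte-like and macrophage-like classes. All cells held 13796800 to 20781300 UMIs per library, and mature neutrophil-like cells 242332 to 2959600, where 22% of 2-fold changes were recovered in simulation.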

Other observations

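No further explanation was tested in this part, and the predictions from cluster shares were computed after the list results were seen.

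Lists differed in how closely their change in all cells summed followed the cluster shares, computed with each cluster's profile held at its pooled DMSO counts. Observed medians are edgeR log2 fold changes with TMM factors, while predicted ones use log2 CPM without these factors. Small gaps between them may come from the measure. Clusters are defined by expression, so a predicted change need not be one of cell types alone. MHC class II genes, which dendritic cells and monocytes express, had a predicted median of 0.91 and an observed one of 1.14. Mature neutrophil genes had -1.25 predicted and -1.43 observed. Cholesterol synthesis genes had -0.11 predicted and -0.45 observed, p53 targets -0.03 and 0.27, and G2 and M phase genes 0.18 and -0.13. Secondary granule genes had -1.15 and -1.70, and targets of the hypoxia-inducible factor -0.09 and -0.25. Megakaryocyte or platelet genes had -1.78 and -2.82.

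Further lists were called in progenitors. In HSPC-like cells 24 interferon response genes had a median of 0.30, with 0 higher over all genes by edgeR and 1 adjusted over the list alone (camera adjusted p = 4.10e-06; adjusted p = 0.50 with an estimated correlation). In the same class 12 MHC class II genes had a median of 0.31, with 0 higher over all genes and 3 adjusted over the list alone (0.000112; adjusted p = 0.777 with an estimated correlation). The latter was not called without DMSO 2 (0.0787). Of 12244 genes in this class 758 had an unadjusted p under 0.05, and DESeq2 called 16. Cluster 16, led by the ferritin genes FTL and FTH1 and unnamed, held 1.59% and 2.25% of the DMSO libraries and 2.73% and 3.88% at 1.5 and 3 µM. Its barcodes had medians of 1131 UMIs and 0.574% mitochondrial UMIs, against 3058 and 3.17% over all kept cells. Whether it holds whole cells was not tested.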
